A study of Homo sapiens with 6 samples.

How the data were processed

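RNA from stem cell-derived cardiomyocytes of 1 line was compared between 3 DMSO and 3 doxorubicin libraries (1 µM, 24 h). Per the labels' protocols, total RNA was extracted with a column kit and polyadenylated RNA was made into libraries with a TruSeq stranded mRNA kit. The submitters' processing notes name STAR, a read aligner, and the GRCh38 build. The program that counted reads per gene, its annotation, its use of strand and all versions are not given in the sources used here.

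The values the authors deposited are expected or estimated counts per gene symbol, 1 table per library, each with 26364 symbols. They are not all whole: between 71.677% and 80.655% of the values in a library were whole to within a millionth, and the rest held fractions, as when a read is divided among several genes. They were rounded to whole numbers before any test. None of 13 mitochondrially encoded genes was found among the symbols. Symbols were matched to GENCODE release 29 on GRCh38, 23712 directly and 762 through older names, and 1890 stayed unmatched; coordinates are 1-based from that annotation. Genes on chromosome Y and the X-inactivation transcript entered the fits but are not reported.

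Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group, TMM factors, a quasi-likelihood fit with robust dispersion, and Benjamini-Hochberg adjustment over the 17891 genes that passed the filter. Standard errors were taken as the absolute log2 fold change over the root of the F statistic. Gene lists were tested 2-sided with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 33 of 34 lists with at least 5 tested members; the list without them was that of mitochondrially encoded genes. Each list's counts of changed genes were also adjusted over the list alone. Camera compares a list with all other genes. Some genes belong to more than 1 list.

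The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold, with a mean of at least 10 CPM, non-overlapping groups and a real symbol; a fixed set of genes known from doxorubicin and heart biology; and, per list, up to 4 members with the largest change among those past the threshold with a mean of at least 1 CPM. It gave 171 genes, of which the informative ones are described and some are not reported here.

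A fold against a group at 0 was computed against a floor of 3 counts over the whole group (0.0209 CPM in DMSO), and genes with 1 to 3 counts in DMSO were given a ratio with an exact 95% binomial interval. Without molecular identifiers these intervals and floors cover counting error only. The floor of a single library lay between 0.048 and 0.0787 CPM.

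The fit was tested on simulated counts with the real means, dispersions and library sizes, 17891 genes and 200 changed genes. For doxorubicin against DMSO it recovered 4% of genes changed 1.5-fold, 48% of those changed 2-fold, 88% of those changed 4-fold and 98% of those changed 8-fold, and called 11 of 17691 unchanged genes. Far more genes were called in the data, where the adjusted threshold is therefore less strict, so these shares do not give the recovery there. Camera called 15 of 15 simulated shifted lists and 1 of 15 unshifted ones. The simulated genes varied independently, so this does not give the error rate for lists whose genes vary together.

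Alternatives were DESeq2 size factors, upper quartile factors or library size alone, no filter or at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a non-robust dispersion, the replicate number as a block, and leaving out each library; for lists, an estimated correlation and fry. A fit restricted to genes with whole values and tests of symbol families were added after seeing the data. Figures were drawn with matplotlib 3.10.9.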

Results

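Polyadenylated RNA was sequenced from human pluripotent stem cell-derived cardiomyocytes of the line SCVI-273, labelled as wild type, after 24 h with 1 µM doxorubicin or with the solvent DMSO. Doxorubicin is an anthracycline used against cancer that poisons type II topoisomerases and intercalates into DNA, and its use is limited by damage to the heart. The DMSO group and the doxorubicin group held 3 libraries each. Estimated counts summed to 41182402, 66212426 and 46585252 in DMSO replicates 1, 2 and 3, and to 38239627, 52302916 and 63048514 in doxorubicin replicates 1, 2 and 3. The labels do not say whether the replicates came from separate differentiations or cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as TMM-scaled CPM (counts divided by the scaled library total), as mean ± SD with n = 3 per group, and changes as log2 fold changes of doxorubicin over DMSO with their standard errors.

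Libraries of the same group resembled each other more than libraries of different groups. Pearson correlations of log2 CPM, which are taken across genes and so not across independent replicates, lay between 0.986 and 0.9882 within DMSO and between 0.8012 and 0.8361 across groups. Doxorubicin replicates 1 and 2 correlated at 0.9899, whereas doxorubicin replicate 3 correlated with them at 0.9617 and 0.9654. The first principal component held 87.51% of the variance and separated the groups, and the second held 6.265% and separated doxorubicin replicate 3 from the other doxorubicin libraries. No pair of libraries agreed within sampling noise, as the smallest chi-square per degree of freedom between 2 libraries was 12.45.

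**Figure D1:**
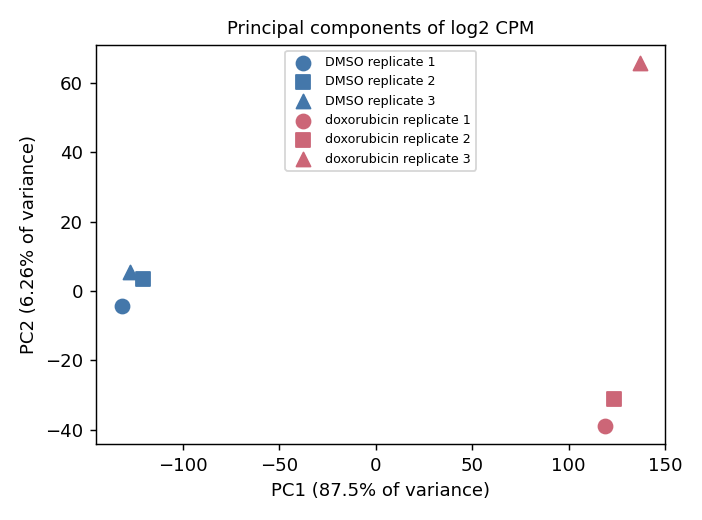
Principal components of log2 CPM over the genes tested, with PC1 (87.51% of the variance) on the x axis and PC2 (6.265%) on the y axis. Each point is 1 library, colours are the groups and shapes the replicates; doxorubicin replicate 3 lies at 65.81 on PC2, and the other doxorubicin libraries at -38.992 and -31.156.

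The comparison of doxorubicin with DMSO asks how the drug changed gene expression across the transcriptome. Of 17891 genes tested, 6315 rose and 5717 fell after doxorubicin at an adjusted p under 0.05 in edgeR's quasi-likelihood test. With an absolute log2 fold change of at least 1, 4683 rose and 3611 fell. The groups did not overlap in 11945 of the 12032 genes called, and in 74.3% of all genes tested, where chance gives 10%. Without doxorubicin replicate 3, 7130 genes rose and 6898 fell. With the total library size as the only scaling, all fold changes moved up by a median of 0.208 on the log2 scale, so directions below are relative to the TMM scaling, and smaller changes in particular depend on it.

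**Figure D2:**
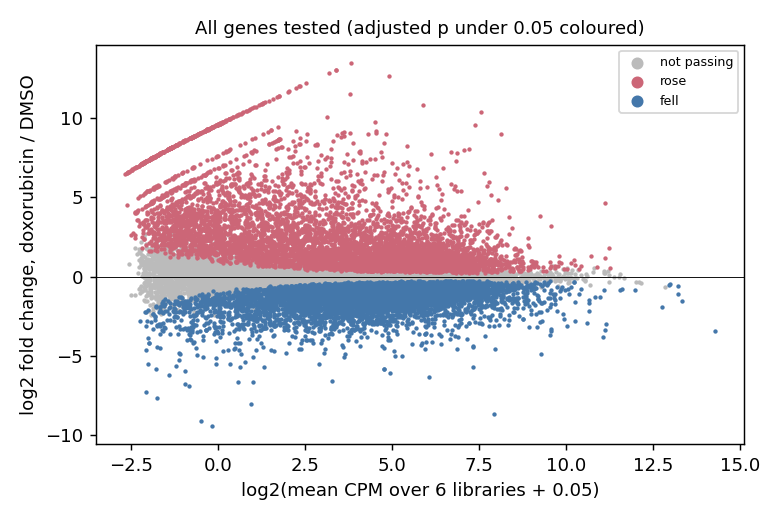
Log2 fold change of doxorubicin over DMSO (y axis) against the log2 of the mean CPM over 6 libraries plus a small constant (x axis), with 1 point per gene tested. Genes that rose and fell are coloured and grey genes did not pass; the straight lines of points at the upper left are genes with 0 or few counts in DMSO, whose fitted fold changes depend on the prior count.

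Among genes with a mean of at least 10 CPM and groups that did not overlap, LRRC10 had the largest decrease. This cardiac leucine-rich repeat protein gene on chromosome 12 (69608564 to 69611162, GRCh38) fell from 483.8 ± 31.4 to 1.203 ± 0.165 CPM, a log2 fold change of -8.65 (SE 0.168, adjusted p = 7.4e-07). FBXO40 and ASB2, which encode muscle-expressed subunits of ubiquitin ligases, changed by -6.31 (SE 0.394) and -5.69 (SE 0.313). MIR133A1HG, the host gene of the muscle microRNA miR-133a-1, changed by -6.11, and FBXL22, another F-box gene, by -5.85. MIR133A1HG is annotated as antisense, and how the counting used strand is not given in the sources used here. Its value is therefore uncertain. KCNJ11, which encodes a pore subunit of ATP-sensitive potassium channels, fell from 23.61 ± 1.47 to 0.7212 ± 0.267 CPM, and FHL2, a LIM domain gene, from 1202 ± 114 to 40.06 ± 6.25 CPM. The other genes among the 12 with the largest decreases were PRSS42 (-5.84), EPN3 (-5.01), TGFB1I1 (-5.00), DISC2 (-4.90) and PNMAL1 (-4.69). Without doxorubicin replicate 3, PRSS42 stood at -6.57 and PNMAL1 at -5.38.

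The genes with the largest increases were close to silent in DMSO. INHBB, which encodes an inhibin and activin subunit on chromosome 2 (120346143 to 120351808, GRCh38), had 0 counts in all DMSO libraries and reached 28.13 ± 4.85 CPM, at least 1345-fold higher than the floor of 3 counts over the DMSO group. On the same floor, DIO3, a deiodinase that inactivates thyroid hormone, was at least 992.6-fold higher and ITGAM, an integrin subunit best known from myeloid cells, at least 990.2-fold higher. KCNA1, a voltage-gated potassium channel gene, rose from 0.06455 ± 0.0248 to 117.2 ± 17.4 CPM, a log2 fold change of 10.81 (SE 0.261, adjusted p = 1.29e-06). FAM131B (9.19) and the transcription factor genes SIX2 (9.09) and POU3F1 (9.09) also rose. INSM2, with 1 count in DMSO, had a ratio of 9522 with a 95% counting interval of 1710 to 376000, and EOMES, a T-box factor gene also with 1 count, had a ratio of 4379 (786 to 173000). FOSB rose by 10.41, EGR2 by 9.54 and the inducible heat shock gene HSPA6 by 9.08. HSPA6 is uncertain because near-identical genes can share its reads.

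Single libraries set the size of several of these increases. Without doxorubicin replicate 3 the fitted log2 fold change went from 13.06 to 11.54 for DIO3 and from 13.05 to 12.37 for ITGAM. As both had 0 counts in DMSO, these values depend on the prior count. INSM2 went from 12.63 to 10.34 and EOMES from 11.52 to 9.79. FOSB stood at 8.99, EGR2 at 7.71 and HSPA6 at 7.43 without that library. Without DMSO replicate 2 the log2 fold changes were 14.49 for INSM2, 10.87 for EOMES and 10.89 for POU3F1. Without DMSO replicate 3 they were 10.09 for SIX2 and 10.11 for HSPA6, and without DMSO replicate 1 EOMES stood at 13.53. The values of 14.49 and 13.53 depend on the prior count, because the library left out held the gene's only DMSO count. INSM2 missed the threshold in limma-voom, with an adjusted p = 0.0504.

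Most genes of the contractile apparatus fell. Of 30 sarcomere genes tested, 25 fell and none rose, and 26 fell when adjusted over the list alone; the median log2 fold change was -1.39 (camera adjusted p = 8.2e-07, and adjusted p = 0.855 with an estimated correlation). MYH7, the beta myosin heavy chain, changed by -3.46 (SE 0.511), from 36470 ± 2880 to 3320 ± 2540 CPM, and MYH6, the alpha chain, by -2.79 (SE 0.36). LMOD2, which controls thin filament length, changed by -4.54, TNNI3 by -3.02, SMYD1 by -2.94, the titin gene TTN by -1.53 and ACTN2 by -0.79. TNNT2 did not pass, at -0.69 (SE 0.286, adjusted p = 0.0648). It passed in 5 of the alternative fits, among them DESeq2 (adjusted p = 0.036), limma-voom (0.0314) and the fit with the replicate number as a block (0.0246). Doxorubicin replicate 3 lay above both other doxorubicin libraries in 28 of the 30 genes, and without it the values were -4.30 for MYH7, -3.67 for TNNI3 and -1.11 for TNNT2 (adjusted p = 8.07e-09). The MYH7 locus also holds the antisense gene MHRT, whose counts stood at 0.111 to 0.118 of those of MYH7 in all 6 libraries. How the counting used strand is not given in the sources used here, so reads of this pair may be shared and both values are uncertain.

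**Figure D3:**
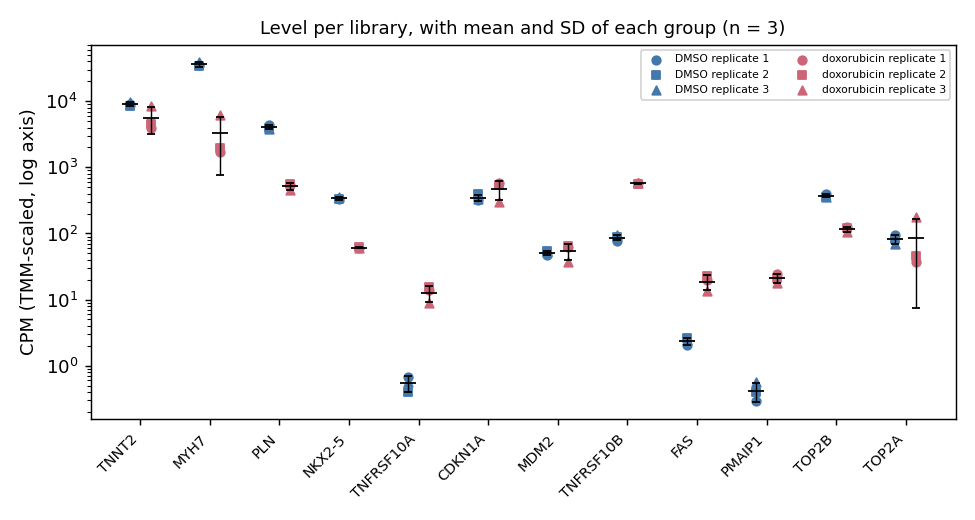
TMM-scaled CPM on a log axis for 12 genes on the x axis, with 1 point per library, colours for the groups and shapes for the replicates; black marks and bars are the mean and SD of each group (n = 3). NKX2-5 lies at 59.74 to 63.46 CPM in the doxorubicin libraries and at 328.4 to 354 CPM in DMSO, while doxorubicin replicate 3 stands apart for TNNT2, MYH7 and TOP2A.

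Genes of excitation and calcium cycling mostly fell as well. Of 31 ion channel and calcium handling genes, 17 fell and 5 rose, the same numbers as when adjusted over the list alone, with a median of -0.81 (camera adjusted p = 0.00439, and adjusted p = 0.855 with an estimated correlation). The sodium-calcium exchanger SLC8A1 changed by -3.30 (SE 0.215), the SERCA inhibitor phospholamban PLN by -2.96 (SE 0.142), the hERG channel gene KCNH2 by -2.36, the calcium release channel RYR2 by -1.37 and the calcium pump ATP2A2 by -1.27. The connexin gene GJA5 changed by -4.01, or -4.64 without doxorubicin replicate 3. KCNJ2, an inward rectifier gene, went the other way, from 0.8332 ± 0.157 to 20.29 ± 9.43 CPM. Doxorubicin replicate 3 lay above the other doxorubicin libraries in 20 of these 31 genes.

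Cardiac transcription factors moved in both directions, with 9 of 20 up and 10 down, adjusted over all genes or over the list alone (median -0.26, camera adjusted p = 0.498). NKX2-5 changed by -2.47 (SE 0.0982), TBX20 by -2.90 and GATA4 by -1.33, and TBX3 (3.38) and NR2F2 (2.70) rose. NR2F1, with 2 counts in DMSO, had a ratio of 295.1 with a 95% counting interval of 81.4 to 2440. Its fitted value of 7.96 became 10.63 without DMSO replicate 2, which held both counts, so that value depends on the prior count. Of 10 cardiac stress genes 3 rose and 5 fell, with the same numbers when adjusted over the list alone (median -0.70, camera adjusted p = 0.656). The natriuretic peptide genes NPPA (0.32, adjusted p = 0.143) and NPPB (-0.23, adjusted p = 0.518) did not pass; NPPA passed without doxorubicin replicate 1 (0.46, adjusted p = 0.0406) and with library size scaling (0.52, adjusted p = 0.0105). ANKRD1 changed by -3.17 and XIRP2 by -3.61, and CTGF rose by 3.48. Without doxorubicin replicate 3 these were -3.05, -4.46 and 2.74.

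Energy metabolism genes were mainly lower. Of 40 nuclear-encoded respiratory chain genes, 32 fell and 1 rose, also when adjusted over the list alone, with a median of -0.91 (camera adjusted p = 6.72e-07, and adjusted p = 0.855 with an estimated correlation). NDUFA8 of complex I changed by -3.57 (SE 0.154) and ATP5C1 of ATP synthase by -3.14 (SE 0.151). Doxorubicin replicate 3 lay above the other doxorubicin libraries in 32 of the 40. Among 26 fatty acid oxidation and PGC-1 genes 14 fell and 2 rose (median -0.54, camera adjusted p = 0.062, so the list did not pass), again the same adjusted over the list alone. PPARGC1A, the transcriptional coactivator PGC-1 alpha, changed by -2.69 and the fatty acid carrier FABP3 by -2.14. The list passed with the replicate block (adjusted p = 0.048), without DMSO replicate 2 (0.0394) and without doxorubicin replicate 3 (0.00756). Of 22 glycolysis genes 12 fell and 3 rose, as when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.0458, and adjusted p = 0.855 with an estimated correlation). Doxorubicin replicate 3 lay above the other doxorubicin libraries in 17 of the 22. ALDOC (-2.69) and PGAM2 (-2.35) fell, and the hexokinase gene HK2 (3.22) and PFKFB3 (2.78) rose. The glycolysis call was also lost with DESeq2 size factors (adjusted p = 0.0506), with library size scaling (0.0776), and without DMSO replicate 3 (0.0516), doxorubicin replicate 1 (0.0543) or doxorubicin replicate 2 (0.0569). It stood at an adjusted p = 0.0258 with the replicate block and 0.00349 without doxorubicin replicate 3.

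Most p53 target genes rose, while several well-known targets did not pass. Of 35 p53 target genes 21 rose and 5 fell, the same adjusted over the list alone, with a median of 0.86 (camera adjusted p = 0.0114, and adjusted p = 0.855 with an estimated correlation). PMAIP1, which encodes the BH3-only protein NOXA, rose by 5.66 and PLK3 by 3.93. CDKN1A, the cell cycle inhibitor p21, did not pass at 0.44 (SE 0.233, adjusted p = 0.129), nor did MDM2 at 0.11 (SE 0.21), GDF15 at -0.01 (SE 0.403), BAX at -0.06 (SE 0.189) or BBC3, encoding PUMA, at -0.02 (SE 0.274). Doxorubicin replicate 3 was below the other doxorubicin libraries in 25 of the 35 genes. Without it CDKN1A stood at 0.68 (adjusted p = 1.13e-06) and MDM2 at 0.33 (adjusted p = 0.00212), both past the threshold.

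Of 17 death receptor pathway genes tested, from 20 listed, 10 rose, 2 fell and 5 did not pass, the same adjusted over the list alone. The median was 1.09 (camera adjusted p = 0.0167, and adjusted p = 0.855 with an estimated correlation). FASLG, TNFSF10 and TNF were listed but did not pass the filter. TNFRSF10B, the TRAIL receptor DR5, went from 86.86 ± 8.01 to 570.6 ± 13 CPM (2.72, SE 0.114), TNFRSF10A, or DR4, rose by 4.55 (SE 0.324), the decoy receptor gene TNFRSF10D by 4.71 (SE 0.253), FAS by 2.98 (SE 0.242) and TNFRSF1B by 3.17 (SE 0.401). Doxorubicin replicate 3 lay below both other doxorubicin libraries in 11 of the 17. FAS, TNFRSF10B and TNFRSF10C, which rose, also belong to the p53 list, so these lists are not independent. In the BCL2 family 5 of 16 rose and 5 fell, both adjusted over all genes and adjusted over the list alone (from here on, adjusted either way), with a median of -0.04 and a camera adjusted p = 0.931. The median turned positive with DESeq2 size factors (0.01) and with library size scaling (0.18). Without doxorubicin replicate 3 it was 0.23, and camera's direction turned upward (adjusted p = 0.915). BCL2 rose by 2.40, and BAK1 (-1.88) and BCL2L2 (-1.72) fell.

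Of the drug's targets, TOP2B, the topoisomerase II isoform of non-dividing cells, fell from 370.6 ± 18.9 to 116.4 ± 9.89 CPM (-1.67, SE 0.11). TOP2A did not pass, at 0.08 (SE 0.549, adjusted p = 0.904). Doxorubicin replicate 3 held 178.3 CPM of it against 37.05 and 45.27 in the others, and without that library TOP2A was lower, at -0.99 (adjusted p = 5.23e-06). TOP1 stood at 0.13 (adjusted p = 0.383), and at 0.24 (adjusted p = 0.00748) without that library. In the list of 24 topoisomerase and doxorubicin handling genes 8 rose and 8 fell, adjusted either way, with a median of -0.10 that became 0.12 with library size scaling (camera adjusted p = 0.839). The efflux pump gene ABCB1 rose from 0.1617 ± 0.0703 to 7.429 ± 2.44 CPM and the retinoic acid receptor gene RARG from 5.654 ± 0.315 to 162.4 ± 18.7 CPM. The nucleoside transporter genes SLC28A3 (-3.08) and SLC29A1 (-2.44) and the carbonyl reductase gene CBR1 (-1.55) fell. CBR3 had 0 counts in DMSO and 0.4014 ± 0.0935 CPM after doxorubicin, at least 19.2-fold higher.

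All 44 replication-dependent histone genes tested rose, adjusted over all genes or over the list alone, with a median of 5.35 (camera adjusted p = 2.83e-11, and adjusted p = 0.051 with an estimated correlation); 5 of them were at 0 in DMSO, and the median was the same with these at their bound. HIST1H1A was at least 133.9-fold higher and HIST1H3I at least 104.8-fold higher. HIST1H1D rose by 9.04, or 8.15 without doxorubicin replicate 3 and 10.03 without DMSO replicate 3, and HIST1H3J by 8.92, or 9.64 without DMSO replicate 2. HIST1H3I also depended on doxorubicin replicate 3, with fitted values of 9.82 with it and 8.87 without. Of the 44 genes, 16 had whole deposited values in all 6 libraries, HIST1H1A and HIST1H1D among them. The others, HIST1H3I and HIST1H3J included, held fractional values, so the split of reads among similar copies is uncertain for them.

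The other cell cycle lists held genes that rose and genes that fell. Of 30 S phase genes 11 rose and 10 fell, adjusted either way; the median was -0.08, and 0.12 with library size scaling, while camera gave the opposite direction to the median (adjusted p = 0.931). CCNE2 (4.04) and CCNE1 (1.68), encoding cyclins of S phase entry, rose, and the replication genes MCM2 (-1.82) and RRM2 (-1.73) fell. Of 31 G2 and M phase genes 21 fell and 4 rose, adjusted either way, with a median of -0.99 (camera adjusted p = 0.00214, and adjusted p = 0.855 with an estimated correlation). CENPE (-3.24), NUF2 (-2.90) and the proliferation marker MKI67 (-1.40) fell. AURKA (3.40) and NUSAP1 (2.95) rose, and stood at 2.21 and 1.81 without doxorubicin replicate 3, which lay above the other doxorubicin libraries in 23 of the 31. Among 30 double-strand break repair genes 8 rose and 12 fell, adjusted either way, with a median of -0.19, or 0.02 with library size scaling (camera adjusted p = 0.537). RAD50 (-2.57) and NBN (-1.84), members of the break-sensing MRN complex, fell and XRCC3 (1.79) rose. BLM (-1.73, adjusted p = 0.0313) lost its call without DMSO replicate 1 (adjusted p = 0.0762), DMSO replicate 2 (0.0795), DMSO replicate 3 (0.0607) or doxorubicin replicate 1 (0.0726), and stood at -2.59 without doxorubicin replicate 3.

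**Figure D4:**
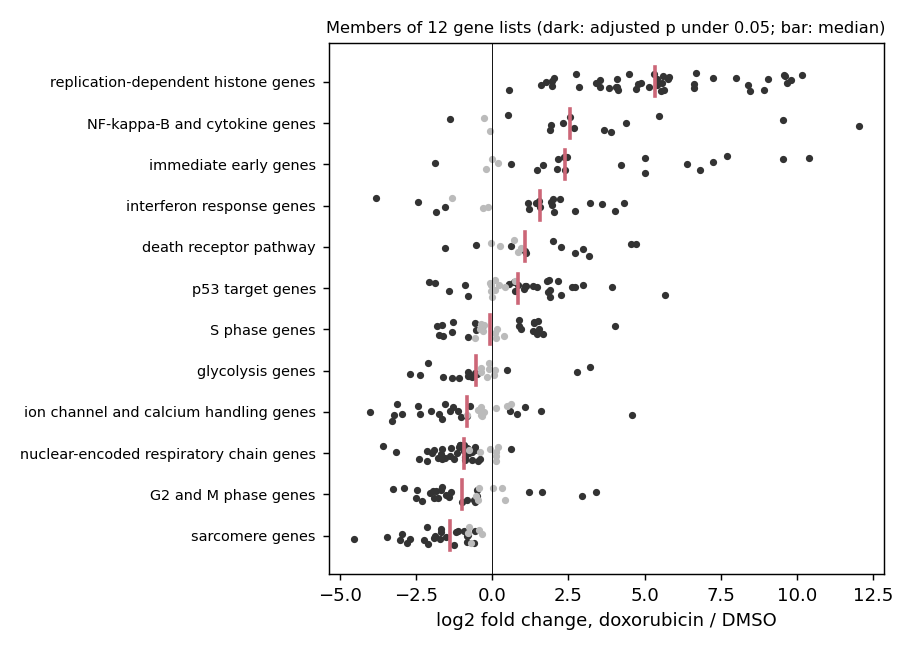
Log2 fold changes of doxorubicin over DMSO (x axis) for the tested members of 12 gene lists (y axis). Each point is 1 gene, dark where its adjusted p was under 0.05, and the bar is the list's median; all 44 histone genes lie to the right of 0, and the sarcomere genes have a median of -1.39.

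Most immediate early genes rose, as did most of the cytokine genes tested. Of 21 immediate early genes 17 rose and 1 fell, adjusted either way, with a median of 2.39 (camera adjusted p = 0.00106, and adjusted p = 0.855 with an estimated correlation), and doxorubicin replicate 3 lay above the other doxorubicin libraries in 19. FOSL1 rose by 7.70 and KLF4 by 7.25, or 8.87 and 9.72 without DMSO replicate 3. Of 24 NF-kappa-B and cytokine genes listed, 15 passed the filter, and of these 12 rose and 1 fell, adjusted either way. Their median was 2.55, the same with the 2 genes at 0 in DMSO set to their bound (camera adjusted p = 0.0236, and adjusted p = 0.721 with an estimated correlation). A gene silent in DMSO passes the filter only if it is expressed after doxorubicin, so such members can only rise. ICAM1 rose from 0.9982 ± 0.36 to 21.53 ± 1.42 CPM, IL11 by 5.47 and LIF by 3.90, or 2.94 without doxorubicin replicate 3. CXCL3 was at 0 in DMSO and at least 484.3-fold higher after doxorubicin, with fitted values of 12.02, and 9.38 without doxorubicin replicate 3. Of 22 interferon response genes 15 rose and 4 fell, adjusted either way (median 1.56), but the list did not pass (camera adjusted p = 0.135). IRF1 rose by 3.21, IFI27 by 3.61 and IRF7 by 4.32, or 3.62 without doxorubicin replicate 3, whereas IFIT1 fell from 221.8 ± 3.69 to 15.83 ± 3.9 CPM.

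Stress lists moved in both directions and none of them passed camera. Of 22 integrated stress and ER stress genes 9 rose and 8 fell, adjusted either way (median 0.20, adjusted p = 0.931). ATF3 (3.25), EDEM1 (2.77), ERN1 (2.63) and DDIT4 (2.86) rose, DDIT4 at 1.42 without doxorubicin replicate 3; without that library the list's median was -0.27. Of 16 heat shock genes 7 rose and 5 fell, adjusted either way, with a median of -0.04 that was 0.01 with DESeq2 size factors and 0.16 with library size scaling, and an upward camera direction (adjusted p = 0.929). HSPH1 (2.01) and HSPA8 (1.78) rose, as did HSPA1B (1.72), whose reads can be shared with its near-identical copy, and the cardiac small heat shock gene HSPB7 changed by -3.84 (SE 0.131). Of 23 antioxidant and NRF2 target genes 8 rose and 4 fell, or 6 and 2 adjusted over the list alone (median 0.18, adjusted p = 0.656). NFE2L2, encoding NRF2, rose by 1.24 and GCLC by 1.27, and the ferritin light chain gene FTL changed by -1.57. Of 17 ferroptosis genes 8 rose and 3 fell, adjusted either way (median 0.55, adjusted p = 0.683), with SAT1 at 3.08, SLC3A2 at 1.26 and the iron exporter gene SLC40A1 at -1.71. Of 26 autophagy and lysosome genes 9 rose and 7 fell, adjusted either way, with a median of -0.07, or 0.14 with library size scaling, against an upward camera direction (adjusted p = 0.931). MAP1LC3B (2.43) and CTSB (1.89) rose and GABARAPL1 (-2.47) fell. Of 18 cholesterol synthesis genes 12 fell and 3 rose, adjusted either way (median -0.77, adjusted p = 0.0545). MVK (-3.23) and DHCR7 (-2.72) fell and INSIG1 (2.65) rose. The cholesterol list passed with the replicate block (adjusted p = 0.048), without DMSO replicate 2 (0.0314) and without doxorubicin replicate 3 (0.0265).

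None of the lists of other cell type markers passed camera. With fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, neural markers (adjusted p = 0.00276) and endoderm and liver markers (0.0152) passed upward and epicardial markers (0.0333) downward. Of 18 fibroblast and matrix markers 7 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.56, camera adjusted p = 0.179); PDGFRA (2.20) and DDR2 (3.05) rose and COL1A1 (-0.73) fell. Doxorubicin replicate 3 lay above the other doxorubicin libraries in 17 of the 18, and in all 12 smooth muscle markers. Of those 12, 1 rose and 3 fell, adjusted either way, with a median of -0.16, or 0.03 with library size scaling (adjusted p = 0.592); LMOD1 changed by -3.60 and MYH11 by 1.13. Of 16 endothelial markers 5 rose and 4 fell, or 3 and 4 adjusted over the list alone (median 0.31, adjusted p = 0.931), with FLT1 at 3.66 and KDR at -2.10. Of 10 epicardial markers 3 rose and 3 fell, adjusted either way, with a median of -0.08, or 0.14 with library size scaling (adjusted p = 0.931); ALDH1A2 rose by 5.49, or 6.18 without DMSO replicate 3, and KRT18 changed by -2.33. Of 7 pluripotency markers tested, from 12 listed, 2 rose and 1 fell, adjusted either way (median 0.25, adjusted p = 0.896), with LIN28B at 2.58 and TDGF1 at -1.68. Of 7 endoderm and liver markers tested, from 17 listed, 5 rose and none fell, or 6 and none adjusted over the list alone (median 3.42, adjusted p = 0.0714). Without doxorubicin replicate 3 the median was 2.14 (adjusted p = 0.399). Of 8 neural markers tested, from 15 listed, 5 rose and 1 fell, adjusted either way (median 1.84, adjusted p = 0.148). In these lists, too, a marker silent in DMSO was tested only if expressed after doxorubicin. The neuronal tubulin gene TUBB3 rose from 5.899 ± 0.295 to 244.7 ± 6.93 CPM (5.37, SE 0.115), and NES changed by -1.64. Of 10 skeletal muscle markers 2 rose and 1 fell, adjusted either way (median -0.24, adjusted p = 0.931), with MYH3 at 2.11. Of 14 reference genes 5 rose and 4 fell, adjusted either way, with a median of 0.12, or -0.03 without doxorubicin replicate 3, against a downward camera direction (adjusted p = 0.931), and ACTB, often used as a constant control, fell from 337.3 ± 12.9 to 42.18 ± 11.5 CPM.

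In all, 10 of the 33 lists with enough tested members passed camera with its preset correlation. With an estimated correlation none of the 10 passed. Besides the 10 and the 3 marker lists, fry passed antioxidant (adjusted p = 0.00215), ferroptosis (0.0333), autophagy (0.000515) and interferon response genes (0.00147) upward, and cardiac transcription factors (0.00101), cholesterol synthesis (0.00261), double-strand break repair (0.0207) and fatty acid oxidation genes (0.0208) downward. The counts of members that rose or fell do not rest on that correlation, but they need to be read against all genes tested. Of those 17891 genes, 6315 rose and 5717 fell. The S phase genes (11 and 10 of 30), the BCL2 family (5 and 5 of 16) and the autophagy genes (9 and 7 of 26) lay near these shares. Their counts therefore do not set them apart from other genes.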

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

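The alternatives were planned, except the fit on genes with whole deposited values, which was chosen after seeing the data. Across 3 scalings, 2 tests, no filter, non-robust dispersion and left-out libraries, the number of changed genes stayed within 1.5 times of 12032, and no called gene was called in the opposite direction. Leaving out 1 library gave 10657 to 14028 genes (5719 to 7130 higher and 4713 to 6898 lower), with the highest without doxorubicin replicate 3. A minimum of 10 CPM in 3 libraries gave 7631 genes (3920 higher, 3711 lower) and whole values alone 4864 (2637 higher, 2227 lower); both test fewer genes, 10614 and 7215. Library size scaling moved the share of higher genes from 52.5% to 60.5%.

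Of the 33 lists 10 passed, none with an estimated correlation, where 0 passed, and 21 with fry, which does not compare a list with other genes; the cause was not tested further. The lowest correlation within a group was 0.9617, and 0.8756 over the 500 most variable genes. TOP2A was the only named gene to turn direction with a call: leaving out 1 library gave -0.99 (without doxorubicin replicate 3) to 0.43.

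The replicate numbers share no source in the labels. Deviations from the group means correlated at 0.079, -0.018 and 0.047 for numbers 1, 2 and 3, and 4 of 6 libraries correlated best with their own number. As the labels give no shared source and these correlations were weak, the numbers are not treated as pairs. With the replicate block 11672 genes changed (6026 higher, 5646 lower). The planned fit without mitochondrially encoded genes was not run, as none was found. With 3 libraries per group, 48% of simulated 2-fold changes were recovered. Far more genes were called in the data than were changed in the simulation, so this share does not give the recovery there. How many modest changes were missed in the data is therefore not known.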

Other observations

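The symbol families, the tests on genomic DNA, S phase and the admixture and cell share of doxorubicin replicate 3 were chosen after the results were seen; the tests of read sharing, depth and abundant genes were written before their results. In all, 14 sets of symbols were tabulated and 13 had enough members for camera. Most tested genes of several families of developmental regulators rose. Family members silent in DMSO were tested only if expressed after doxorubicin, so those could only rise. Of 48 forkhead genes tested 39 rose and 2 fell (median log2 fold change 3.33, camera adjusted p = 9.21e-07, and adjusted p = 0.262 with an estimated correlation). Of 12 DLX, PAX and sine oculis homeobox genes 10 rose and none fell (median 6.14, or 5.54 with the gene at 0 in DMSO at its bound, adjusted p = 0.00277, and 0.344 with an estimated correlation), and of 15 WNT ligand genes 12 rose and 1 fell (median 3.85, adjusted p = 0.00159, and 0.262 with an estimated correlation). Of 14 KLF genes 11 rose and none fell (median 1.38, adjusted p = 0.00288, and 0.262 with an estimated correlation). Of 18 SOX genes 14 rose and 1 fell (median 3.05, adjusted p = 0.00288, and 0.381 with an estimated correlation), with a median of 1.94 without doxorubicin replicate 3. In the HOX family 5 of 10 rose and 5 did not pass (median 2.47, adjusted p = 0.0395, and 0.368 with an estimated correlation). The 4 ID genes, inhibitors of bHLH factors, rose, too few for camera. ID1 stood at 7.52, or 6.61 without doxorubicin replicate 3 and 8.22 without DMSO replicate 2, and ID2 at 5.84, or 5.02 without doxorubicin replicate 3. ID3 (1.71) lost its call without DMSO replicate 1 (adjusted p = 0.0919) or DMSO replicate 2 (0.0725), and stood at 0.80 without doxorubicin replicate 3. FOXC1 went from 0.066 ± 0.0642 to 39.26 ± 25 CPM, a fitted 8.98, or 8.31 without doxorubicin replicate 3 and 9.99 without DMSO replicate 2.

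In 5 other families more members fell than rose. Of 81 mitochondrial ribosomal protein genes 65 fell and 5 rose (median -1.06, camera adjusted p = 1.51e-10, and adjusted p = 0.262 with an estimated correlation), with MRPL27 at -3.55, and of 17 tRNA synthetase genes 12 fell and 1 rose (median -0.61, adjusted p = 0.00246, and 0.262 with an estimated correlation), with AARS at -2.78. Of 12 SR splicing factor genes 8 fell and 1 rose (median -0.61, adjusted p = 0.0115, and 0.368 with an estimated correlation), with SRSF3 at -3.75. Of 57 clustered protocadherin genes 48 fell and none rose (median -1.34, camera adjusted p = 3.98e-09, and 0.344 with an estimated correlation). Some of these genes share exons, so the split of reads among those is uncertain. Of 82 cytosolic ribosomal protein genes 28 fell, 2 rose and 52 did not pass (median -0.16, adjusted p = 0.0108, and 0.651 with an estimated correlation), and with library size scaling the median was 0.043 (adjusted p = 0.351). None of the families passed with an estimated correlation.

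With 3 libraries per group only 10 splits exist, too few for a share under 0.05. The real split gave 12032 genes and the highest other split 0. For lists with the preset correlation, the real split gave 10 and other splits up to 12, and 5 of the 10 splits, the real one included, gave at least 10. The number of lists that passed was thus no larger than in some other splits. Every other split mixes both treatments within each group in unequal numbers, so it still carries part of the treatment difference. That difference also widens the spread within its groups. The list and gene counts of these splits therefore do not show what libraries without a treatment difference would give, and no conclusion is drawn from them.

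The rise of all 44 replication-dependent histone genes in polyadenylated RNA is unusual, since their transcripts normally end without a poly(A) tail. The histone genes gained a median of 10.32 CPM per kb. In doxorubicin libraries 81 single-exon keratin-associated protein genes held at most 0.04156 CPM per kb and 372 olfactory receptor genes at most 0.03443. Genomic DNA in those libraries would raise all these genes alike per kb, so it is argued against. A larger share of cells in S phase would raise S phase genes alike, and their median was -0.084 (SD 1.32) against 5.35. Of the histone genes with whole values in all libraries 16 of 16 rose, a count that was fixed once all 44 had risen. Their median log2 fold change was 5.087, close to the 5.35 of all 44, which argues against read sharing among copies as the whole cause. A response of the cells to doxorubicin stays open, as untested, and so do causes not examined here, technical ones included.

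Doxorubicin replicate 3 stood apart from replicates 1 and 2. Depth is argued against, because thinned to the total of replicate 1 it still correlated with them at no more than 0.965, against 0.9901 between them. DMSO RNA mixed into it would have to make up 12.7% to give its MYH7 level, and 189 of 2585 fallen genes held a smaller share of their DMSO level than that, so admixture alone does not account for it; replicate 3 lay nearer to DMSO in 67.5% of 3942 genes that fell, the way admixture predicts, but in 48.1% of 4734 genes that rose. A larger share of cardiomyocytes would raise sarcomere genes, and 28 of 30 were above both other libraries, but 29 of 30 fibroblast and smooth muscle markers were too, a comparison added after the sarcomere count was seen. As cardiomyocytes express some of those markers, a different cell makeup and a different stage of response cannot be told apart.

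More protein-coding genes were detected after doxorubicin, 16726 to 17640 per library against 15440 to 15985. Without the 100 most abundant genes and thinned to 1 total, the lowest doxorubicin library still had 16618 and the highest DMSO library 15736, which argues against depth or a few abundant genes. Genomic DNA and expression cannot be told apart. The olfactory receptor genes held 0.01531 to 0.03443 CPM per kb in doxorubicin libraries against 0.005571 to 0.007274 in DMSO. Genomic DNA predicts this, but expression of these genes would give it too. The keratin-associated protein genes went the opposite way, with 0.01842 to 0.04156 against 0.04782 to 0.06326. In DMSO they lay above the olfactory receptor genes, so they may not have been silent there. Their fall therefore does not count against genomic DNA. Single-exon protein-coding genes had a median log2 fold change of 1.51 (417 genes) against -0.01 in multi-exon genes (14876), with camera adjusted p = 6.42e-05, and 0.111 with an estimated correlation. Without the histone genes the median of the other 356 was 0.92, with 192 up and 81 down (camera adjusted p = 0.00277, and 0.23 with an estimated correlation). Of the 417 genes 27 were at 0 in a group, and of the 356 genes 19. Both medians were the same with these at their bound. Genes silent in DMSO were tested only if expressed after doxorubicin, so those could only rise. How many multi-exon genes were at 0 in a group was not counted.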
